A study of Mus musculus with 6 samples.

How the data were processed

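The material was autopod tissue, the part of the limb that forms the hand or foot plate, from C57BL/6 mouse embryos at embryonic day 14.5. Per the labels' protocols, 2 control and 2 mutant littermate embryos were frozen and sectioned, and cells of 3 tissues were taken by laser-capture microdissection. The tissues were the interzone, which is the cell band between 2 future skeletal elements, the growth plate cartilage beside it, and the tissue between the digits. The mutant is named Tgfbr2Prx1KO, by convention a deletion of the TGF-beta type II receptor gene Tgfbr2 in limb mesenchyme through a Prx1-driven recombinase. Per the labels' protocols, the captured RNA was turned into cDNA and amplified by PCR with an undisclosed commercial procedure (SuperAmp), and 250 ng of product were labelled with the dye Cy3. Which animals and how many cells stood behind each array is not given in the sources used here.

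There were 6 arrays, 1 for each of the 3 tissues in each of the 2 genotypes, with 1 dye per array. Groups came from the titles, because the descriptions of 5 samples named irradiated human blood, while the titles, the organism and the other labels of those samples named mouse limb tissue. The title of the interdigital mutant sample spelled the mutant without part of the gene name, and its genotype label gave the full name. Per the file headers, the arrays held the same mouse design, were read with Agilent Feature Extraction 9.5.1.1, and lay on 2 slides. Slide 1 held the 3 control arrays and the interzone mutant array, and slide 2 held the growth plate and interdigital mutant arrays. Genotype and slide therefore could not be told apart for the growth plate and interdigital pairs, while the interzone pair lay on 1 slide.

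The scanner files deposited by the authors hold the intensity of each spot, and the processed intensity used here is background-subtracted, per the file headers. The deposited table of values held, for each array, the processed signal divided by that array's median, a linear ratio, as found by setting each column against the scanner values. Each column of that table had a median of 1, and why this scaling was chosen is not given in the sources used here. Control spots and spots marked as outliers were left out, and spots of 1 probe were averaged, which gave 41174 probes per array. The value used was the log2 processed signal minus the array's 75th percentile, so that a level of 0 is the 75th percentile of that array. No spot was saturated. The share of spots well above background, by the scanner software's mark, ranged from 72.3% on the growth plate control array to 88.3% on the interdigital control array.

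Probes were named by matching their accessions, symbols or older symbols to a RefSeq gene table of the assembly GRCm38.p6, which was used for names only. Accessions named 22951 probes, symbols 6659 and older symbols 3109, and 8455 probes had no match and were left out. A gene was represented by its probe with the highest mean over the arrays, which gave 19505 genes. The build behind the probe positions is not given in the sources used here.

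With 1 array per group, a mutant minus control difference within a tissue has no replicate check, and no p-value was computed for it. Genes well above background on both arrays were counted when they differed at least 2-fold. A gene well above background on 1 array of a pair has only a bound, written "at least N-fold", computed against the lowest signal well above background on the dim array or the gene's own signal there, whichever was higher. For each mutant and control pair the 10 genes with the largest difference in each direction were named, if the brighter array was at or above its median of detected probes and the other measured probes of the gene went the same way, and then the 3 brightest bounds in each direction. Members of the fixed lists could be named too. A result that this rule would have given is not reported here. The rule was also set for pairs of tissues, where for length few of its genes are named and the text keeps mostly to list members.

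There were 29 gene lists with 524 entries, of which 516 were on the array. Lists could share genes. They covered interzone and joint, growth plate cartilage, prehypertrophic and hypertrophic cartilage, interdigital mesenchyme, osteoblast and perichondrium, tendon and ligament, skeletal muscle, endothelium, erythroid cells, macrophage, epidermis, and nerve and Schwann cell. The signalling lists were TGF-beta targets, TGF-beta pathway components, BMP and GDF, hedgehog, Wnt, FGF, Notch, and chemokines with their receptors. The remaining lists were matrix proteases and inhibitors, cell cycle, apoptosis, hypoxia and glycolysis, immediate early and stress genes, interferon response, posterior Hox genes, housekeeping and sex-linked genes. A list's median log2 difference was compared with 10000 random lists of the same size matched in 20 bins of mean level, and called lower or higher when it lay outside the middle 95% of them. This describes the arrays and is not a test of the genotypes.

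Additive fits over all 6 arrays were made with limma 3.58.1 in R 4.3.3 with Benjamini-Hochberg adjustment at 0.05. The genotype fit had tissue as a block and used genes detected on at least 3 arrays, and the tissue fits had genotype as a block and used genes detected on at least 2. Each left 2 residual degrees of freedom. The arrays of a genotype came from material of 2 embryos and cannot be taken as independent, and these p-values measure only how alike a difference was across arrays. The number of arrays limits the precision. In 245 probes spotted 10 times per array, the median SD between spots was 0.07 to 0.10 on the log2 scale, which covers the array only and not capture or amplification.

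The limma step was tested on simulated data for the genotype fit over 18028 genes, with 200 genes changed in each of 20 simulations. At the noise of the arrays it recovered 0% of genes changed by 1, 2, 4 or 8 on the log2 scale, with 0.1 false calls per simulation. At a noise 4 times smaller the shares were 1.9%, 72.3%, 92.1% and 98.4%, with 7.5 false calls per simulation. The list step was tested with 40 random lists of 15 genes per pair. Unshifted lists were called in 5%, 2.5% and 2.5% of cases for interzone, growth plate and interdigital tissue. Lists shifted by 1 on the log2 scale were called in 77.5%, 27.5% and 97.5% of cases.

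The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Alternatives were normexp background correction with an offset of 50, quantile normalization, the 75th percentile over probes detected on all arrays, the deposited ratio table, the mean over a gene's probes, other filters on dim probes, a 4-fold threshold, slide as a block, an intensity trend in the variance prior, leaving arrays out, rank correlation, and unmatched random lists. All gene names of the array in the fits, and counts over genes detected on all 6 arrays, were added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.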

Results

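Gene expression was measured on 6 one-colour arrays of laser-captured embryonic mouse autopod tissue, 1 array for each of 3 tissues in control and Tgfbr2Prx1KO mutant embryos. The design asks how loss of TGF-beta signalling in limb mesenchyme alters the interzone, the growth plate and the interdigital tissue, and how these tissues differ. The median processed signal was 349 units on the interzone control array, 103 on the growth plate control array, 466 on the interdigital control array, and 340, 413 and 502 on the matching mutant arrays. Between 72.3% and 88.3% of spots were well above background. Levels are log2 signals relative to the array's 75th percentile, and folds within a tissue compare 1 array with 1 array, with no replicate check.

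Tgfbr2, the gene targeted in the mutant, differed less than 2-fold at its brightest probe in interzone and interdigital tissue and was higher in growth plate. Its level was 2.42 in control and 2.22 in mutant interzone (1.15-fold lower), -2.42 and 1.20 in growth plate (12.3-fold higher), and 2.49 and 1.91 in interdigital tissue (1.49-fold lower). The growth plate control array stood apart at -2.42, while all other arrays lay between 1.20 and 2.49. It also had the lowest share of spots well above background (72.3%) and the lowest median signal (103 units). With 1 array per group, a rise in the growth plate mutant cannot be told apart from a low reading on that control array. The brightest probe lies on chromosome 9 from 115760364 to 115760423, in positions whose build the files do not name. The next probe was 1.91-fold, 3.32-fold and 1.05-fold higher in the 3 mutant arrays, and the dimmest probe, detected on 3 arrays, was 12.1-fold lower in the interdigital mutant. In growth plate that probe went the other way, with a level of -7.17, not well above background, in the control and -5.15 in the mutant, and it was not well above background on either interzone array. The labels do not say which part of the gene was deleted, and a probe outside that part checks nothing.

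In the interzone, where joints form, joint and cartilage genes were lower in the mutant array than in the control array. Gdf5, the growth factor gene that marks the interzone, was 4.74-fold lower, with a level of 4.33 in the control and 2.08 in the mutant. The secreted Wnt modulator gene Sfrp2 was 4.03-fold lower, the transcription factor genes Trps1, Osr2 and Lmx1b were 7.13-fold, 3.28-fold and 9.27-fold lower, and the protease gene Htra1 was 35.0-fold lower. Gdf6, a relative of Gdf5, was at least 27.2-fold lower. Of 24 interzone and joint genes measured, 13 were at least 2-fold lower and 2 higher, and the list median of -1.08 lay below the middle 95% of random lists. Of 26 growth plate cartilage genes, 18 were lower and 1 was higher (median -1.27), among them the matrix genes Matn1 (85.3-fold lower) and Acan (4.24-fold lower) and the cartilage regulator Sox9 (3.51-fold lower).

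Lists for Wnt signalling, hedgehog signalling, tendon and ligament, and cell cycle were also lower in the mutant interzone. Of these calls, only that of cell cycle held under every alternative. Of 24 Wnt genes, 13 were lower and 4 higher (median -1.16), including the secreted antagonists Wif1 (31.4-fold lower) and Sfrp1 (at least 244-fold lower) and the ligand Wnt5a (8.93-fold lower). Of 13 hedgehog genes, 6 were lower and 1 higher (median -0.87), including the receptor and target Ptch1 (4.02-fold lower) and the inhibitor Hhip (21.0-fold lower). Of 13 tendon and ligament genes, 6 were lower and 2 higher (median -0.94), including Tnmd, the tenomodulin gene (at least 39.6-fold lower), and the collagen gene Col12a1 (37.9-fold lower). Of 23 cell cycle genes, 12 were lower and 0 higher (median -1.02), including the mitotic regulator Cdc20 (4.54-fold lower) and the spindle checkpoint gene Bub1b (9.71-fold lower).

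Markers of other cell types were higher in the same mutant interzone array. Of 19 skeletal muscle genes, 11 were higher and 1 lower (median 1.66), with the myogenic regulator Myog 32.0-fold, the cardiac actin gene Actc1 19.3-fold and the muscle myosin light chain gene Myl1 8.93-fold higher. Of 17 macrophage genes, 12 were higher and 2 lower (median 2.42), with the adaptor gene Tyrobp 32.3-fold and the lysosomal marker Cd68 18.2-fold higher, while the leukocyte phosphatase gene Ptprc was 121-fold lower. Of 13 epidermis genes, 11 were higher and 0 lower (median 2.43), with the keratin gene Krt10 366-fold and the cadherin gene Cdh1 52.5-fold higher. Endothelium (8 of 15 higher, median 1.07) and nerve and Schwann cell genes (5 of 10 higher, median 1.02) were called higher too, with the vascular receptor gene Flt1 14.6-fold and the receptor gene Erbb3 12.9-fold higher. Erythroid genes had a median of -0.84, within the range of random lists.

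The largest single differences in the mutant interzone included epidermal genes. Adh1 was 867-fold, Ano9 812-fold, Bnipl 487-fold, Mall 340-fold, Pla2g4f 279-fold, Septin4 269-fold, Tprg 225-fold, and the cornified envelope genes Sprr3 and Hrnr 233-fold and 221-fold higher. Mab21l4, Orm1 and Gsta2 were higher by at least 731-fold, 725-fold and 700-fold. Among lower genes, Fgfrl1, an FGF receptor relative, was 181-fold, Slc5a6 161-fold, the collagen-binding integrin gene Itga11 127-fold, Krt84 123-fold, Lypla1 122-fold, Coa4 115-fold, Chst5 109-fold and Smim3 108-fold lower. Cacna2d3, Myo1c and Tnn were lower by at least 393-fold, 275-fold and 223-fold. Ccl12, which encodes the chemokine MCP-5, was not well above background in the control and had a level of -1.77 in the mutant, at least 37.9-fold higher.

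Over 16668 genes detected on both interzone arrays, 2920 were at least 2-fold higher and 3844 lower in the mutant, and the SD of all differences was 1.66. With normexp background correction the counts were 5340 and 2129, so that 71.5% in place of 43.2% of the genes past 2-fold were higher, and the Wnt list median turned to 0.18; the hedgehog, tendon and ligament, and nerve and Schwann cell calls were each lost under another alternative. With the deposited ratio table the share was 54.3%, and the median of all genes, -0.13, became 0.30 and 0.12 under these alternatives.

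**Figure D1:**
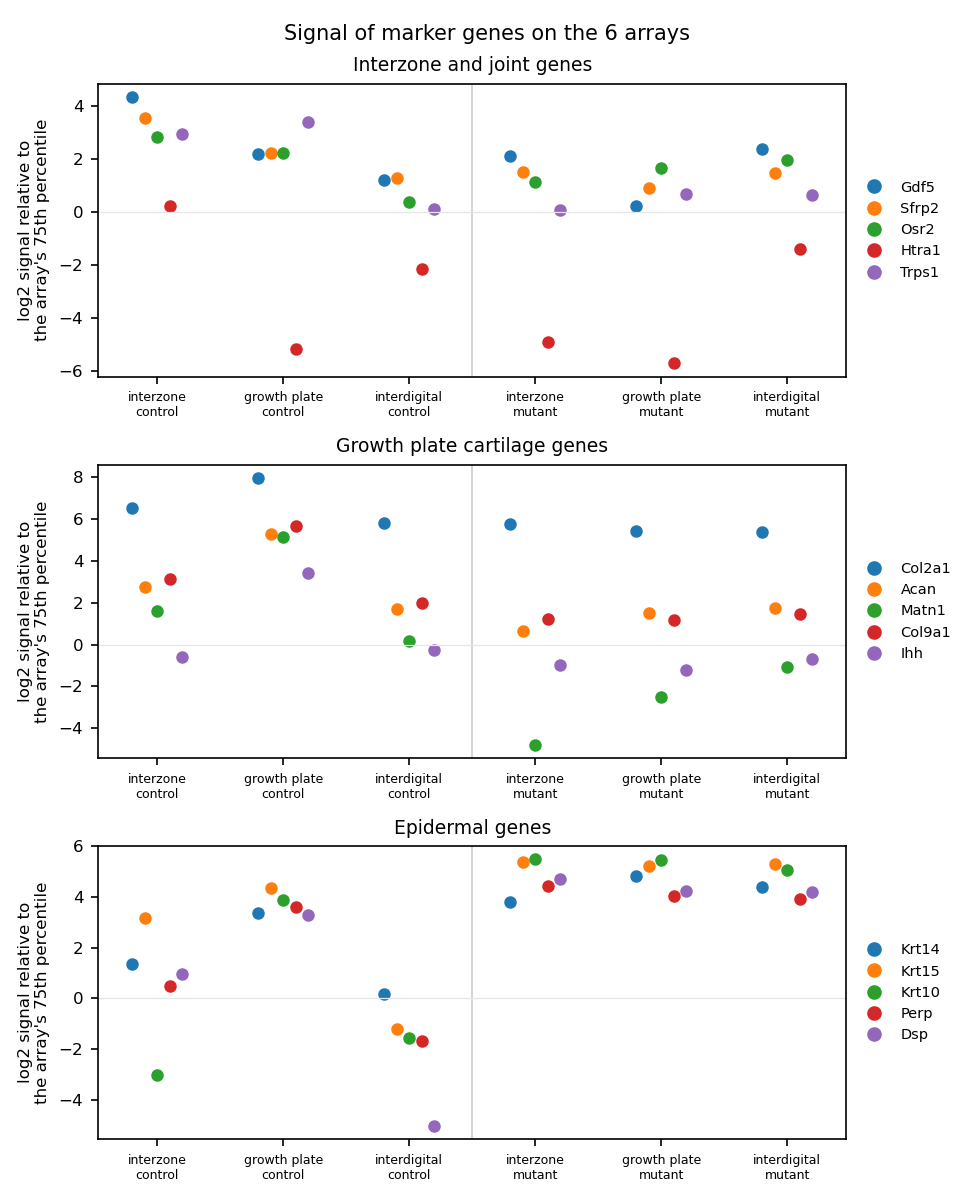
Log2 signal relative to the array's 75th percentile (vertical axis) of 5 interzone and joint, 5 cartilage and 5 epidermal genes on the 6 arrays (horizontal axis), 1 point per gene and array. The cartilage genes are Col2a1, Acan, Matn1 and Col9a1 of the growth plate cartilage list and Ihh of the prehypertrophic and hypertrophic list. Gdf5 was at 4.33 in control and 2.08 in mutant interzone, Matn1 at 5.16 in control and -2.53 in mutant growth plate, and Krt15 at -1.20 in control and 5.29 in mutant interdigital tissue.

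In the growth plate, cartilage genes were lower in the mutant array. Of 26 growth plate cartilage genes, 24 were at least 2-fold lower and 1 higher, and the median of -3.55 lay below the middle 95% of random lists. Col2a1, the main cartilage collagen gene, had a level of 7.96 in the control and 5.43 in the mutant (5.77-fold lower). Acan was 14.0-fold, Col9a1 22.5-fold, Cnmd 27.8-fold, Sox9 11.1-fold, Matn3 147-fold and Matn1 207-fold lower. Of 12 prehypertrophic and hypertrophic genes, 10 were lower and 1 higher (median -2.97), with the hedgehog ligand gene Ihh 24.4-fold, the hypertrophic collagen gene Col10a1 11.5-fold and the channel gene Panx3 25.5-fold lower. The vascular growth factor gene Vegfa was the higher member, at 26.2-fold.

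Other lists were lower in the mutant growth plate array as well. Of 19 muscle genes, 13 were lower and 0 higher (median -1.42), with Myog 28.3-fold and Myl1 13.5-fold lower. Erythroid genes (7 of 10 lower, 2 higher, median -1.34) included the globin gene Hba-a1, 3.24-fold lower. Immediate early and stress genes (8 of 14 lower, 3 higher) had a median of -1.24 and a mean of -0.09, with the phosphatase gene Dusp1 5.20-fold lower and the transcription factor gene Jun 15.5-fold higher. Among TGF-beta targets, Tgfbi was 88.4-fold, Ccn2 28.8-fold and Fn1 4.63-fold lower, while Timp3 was 32.0-fold higher, and the list had a median of -0.43 and a mean of 0.0046, within the random lists. The TGF-beta target medians in interzone (3 of 19 higher, 1 lower, -0.0462) and interdigital tissue (0 of 19 higher, 5 lower, -0.21) were within the random lists as well.

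Endothelial, epidermal, TGF-beta pathway and cell cycle genes were higher in the mutant growth plate array. The endothelium and epidermis calls held under every alternative. The TGF-beta pathway and cell cycle medians turned negative with the deposited ratio table. Of 15 endothelium genes, 9 were higher and 2 lower (median 2.87), with the receptor genes Tie1 and Tek at least 101-fold and at least 86.6-fold and the regulator Sox18 36.0-fold higher. Of 13 epidermis genes, 7 were higher and 0 lower (median 1.48), with the basal keratin gene Krt14 2.78-fold and the adhesion gene Epcam 5.65-fold higher. Of 20 TGF-beta pathway components, 10 were higher and 4 lower (median 1.05), with the endothelial receptor gene Acvrl1 78.5-fold higher and Smad4 5.74-fold lower. Pathway component medians in interzone (4 of 19 higher, 4 lower, -0.0689) and interdigital tissue (2 of 20 higher, 4 lower, -0.15) were within the random lists. Of 23 cell cycle genes, 9 were higher and 4 lower (median 0.50), with the replication helicase gene Mcm7 49.1-fold and Cdc20 3.69-fold higher.

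Among the largest single increases in the mutant growth plate array, the proteasome genes Psmc2 and Psmd1 were 364-fold and 264-fold, the deubiquitinase gene Otub1 404-fold, Tpbg 379-fold, Mybpc1 374-fold, Rnasek 373-fold, Mettl2 372-fold, Capns2 290-fold, the homeobox gene Meis2 244-fold and Rpp30 242-fold higher. Egfl6, Cap1 and Eogt were higher by at least 531-fold, 483-fold and 436-fold. On the growth plate control array Otub1 and Mettl2 had levels of -5.30 and -6.23, against 2.61 and 1.46 on the interdigital control array. Cap1 was not well above background on the first and at 2.07 on the second, while Capns2 was low on both (-5.23 and -3.93). These increases cannot be told apart from low readings on the growth plate control array, which had the lowest detection. Of 13 housekeeping genes, 2 were higher and 3 lower (median -0.30, within the random lists), and the basal transcription factor gene Tbp among them was not well above background in the control and at least 77.7-fold higher in the mutant. Among lower genes, Ppp1r36 was 826-fold, Foxa3 545-fold, Fam205c 453-fold, Olfr1423 393-fold, Dnajc22 360-fold, the leukocyte lysosomal gene Laptm5 335-fold, Tnmd 318-fold, Ell3 306-fold and Rnf208 292-fold lower. The vitamin D receptor gene Vdr, Mttp and Mcoln2 were lower by at least 1615-fold, 1172-fold and 1131-fold. Ccl12 was 1.93-fold lower.

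Over 16166 genes detected on both growth plate arrays, 3606 were at least 2-fold higher and 5189 lower in the mutant, and 1144 were detected in the mutant only against 395 in the control only. The SD of all differences, 2.10, was the widest of the 3 mutant and control pairs. With the deposited ratio table the median of all genes was -1.56 in place of -0.43, 2110 genes were higher and 10446 lower, the share of higher genes was 16.8% in place of 41.0%, and the cell cycle and TGF-beta pathway medians turned to -0.63 and -0.08; the erythroid and the immediate early and stress calls were lost with quantile normalization. That share was 54.4%, with a median of -0.07, when the percentile was taken over probes detected on all arrays, and 53.0% at 4-fold.

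In interdigital tissue, epidermal genes were higher in the mutant array. Of 13 epidermis genes, 11 were at least 2-fold higher and 0 lower, with a median of 5.60. The desmosome gene Dsp was 603-fold, Krt10 97.9-fold, Krt15 89.9-fold and the epithelial p53 target Perp 48.5-fold higher, and Cdh1 and the epidermal regulator Trp63 were at least 286-fold and at least 272-fold higher. The named increases included further epidermal genes, with Ripk4 256-fold, Hrnr 202-fold and the plakophilin gene Pkp1 103-fold higher, beside Endou at 240-fold, Serpinb10 at 128-fold, Frem2 at 125-fold, Capns2 at 107-fold and the ligand gene Wnt10a at 95.2-fold. Grhl1, an epidermal transcription factor gene, and Olah were higher by at least 410-fold and 295-fold.

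Joint genes went the other way from the interzone pair. Of 24 interzone and joint genes, 6 were higher and 3 lower in the mutant interdigital array (median 0.43, called higher), with Lmx1b 5.03-fold, Gdf6 4.07-fold, the hyaluronan synthase gene Has2 3.66-fold, Osr2 2.99-fold and Gdf5 2.26-fold higher. Hypoxia and glycolysis genes (5 of 18 higher, 1 lower, median 0.54) included the carbonic anhydrase gene Car12, 9.28-fold higher, and the glucose transporter gene Slc2a1, 3.44-fold higher. Nerve and Schwann cell genes were called higher (3 of 10 higher, median 0.66), with Erbb3 10.1-fold higher, and their median turned to -0.0535 with the mean over a gene's probes, where the call for joint genes was also lost.

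Skeletal lists were lower in the mutant interdigital array. Of 26 growth plate cartilage genes, 8 were lower and 0 higher (median -0.55), and of 13 prehypertrophic and hypertrophic genes, 7 were lower and 1 higher (median -1.10), with the bone growth factor gene Bmp6 3.27-fold and Panx3 4.28-fold lower. Of 13 osteoblast and perichondrium genes, 6 were lower and 2 higher (median -0.86), with the osteoblast regulators Dlx5 3.40-fold and Sp7 2.83-fold lower. This list shares Runx2, Ibsp, Spp1, Alpl and Sp7 with the hypertrophic list, so the calls of these lists are not independent. Of 17 FGF genes, 5 were lower and 1 higher (median -0.75), with the ligand gene Fgf9 3.04-fold and the feedback inhibitor gene Spry4 12.3-fold lower. Muscle (6 of 19 lower, median -0.75), endothelium (5 of 15 lower, median -0.63) and macrophage genes (6 of 17 lower, median -0.82) were called lower, with the vascular receptor gene Kdr 4.54-fold and the lysozyme gene Lyz2 4.79-fold lower. The cartilage and endothelium calls were lost against random lists not matched on level.

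Among single genes lower in mutant interdigital tissue, C1qtnf9 was 104-fold, Rftn1 97.7-fold, the osteoclast cytokine gene Tnfsf11 84.3-fold, Slfn5 73.4-fold, Romo1 37.7-fold, Atoh7 34.9-fold, the erythroid factor gene Klf1 30.7-fold and Ifi205 28.9-fold lower. Ostn, the chemokine gene Ccl11 and Lmntd1 were lower by at least 157-fold, 115-fold and 90.1-fold. Ccl12 was 7.85-fold lower, and its receptor gene Ccr2 was 4.49-fold lower, against 6.54-fold lower in growth plate and 1.25-fold lower in interzone. Over 17792 genes detected on both arrays, 1811 were higher and 2815 lower, and the SD of all differences was 1.12. The share of higher genes among these was 39.1%, and 51.2% with the deposited ratio table, where the median of all genes was -0.01 in place of -0.17.

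**Figure D2:**
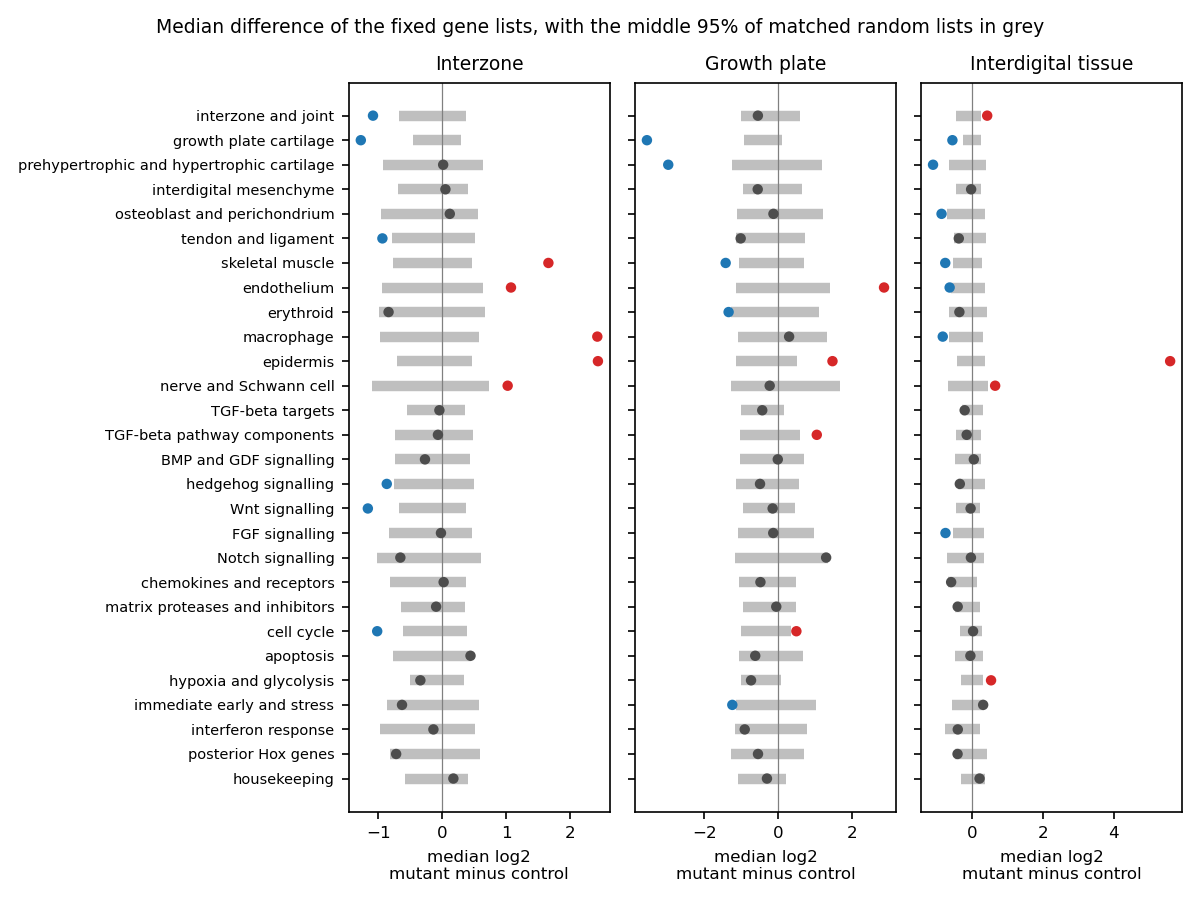
Median log2 difference, mutant minus control, of 28 gene lists (1 point per list) in the 3 tissues, with the middle 95% of 10000 matched random lists as grey bars, red points for lists called higher, blue for lists called lower and horizontal scales that differ between tissues. The cartilage list stood at -1.27, -3.55 and -0.55 and the epidermis list at 2.43, 1.48 and 5.60 in interzone, growth plate and interdigital tissue.

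Mutant differences were little alike between tissues. Across the 15589 genes detected on all 6 arrays, which are not independent replicates, Pearson's r of the mutant minus control differences was 0.08 between interzone and growth plate, 0.16 between interzone and interdigital tissue and 0.17 between growth plate and interdigital tissue. Of these genes, 250 were at least 2-fold higher in all 3 mutant arrays, where 51.2 would be expected for independent tissues, and 297 were lower in all 3, where 159 would be expected. Slide separated the genotypes in 2 of the 3 pairs.

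In the genotype fit over the 3 tissues, limma called 0 of 18028 genes, with 1191 at an unadjusted p under 0.05 and a smallest adjusted p of 0.306. Without the interzone pair, limma called 0 genes, with 670 at an unadjusted p under 0.05 and a smallest adjusted p of 0.756. The leading genes, chosen after their values were seen, were the Y-linked genes Eif2s3y, Uty and Kdm5d, the X inactivation gene Xist and the desmosomal cadherin gene Dsc3, whose log2 difference was 8.36 (SE 0.51, limma adjusted p = 0.306, higher in 3 of 3 pairs), a fitted value against control arrays on which it was not well above background. With adjustment over the list alone, 5 of 13 epidermis genes passed (Krt5, Krt14, Cdh1, Epcam and Krt10, all higher in the mutant), as did Erbb3 in the nerve and Schwann cell list and all 5 sex-linked genes, a total of 11 adjusted over the list alone across the 29 lists. All 26 cartilage genes tested had a lower fitted level in the mutant, and 0 of them passed when adjusted over the list alone. With the deposited ratio table, limma called 12 genes higher and 1 lower.

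The sex-linked genes separated the genotypes in every tissue. Xist had levels of 3.02, 3.97 and 4.14 in control interzone, growth plate and interdigital tissue and of -5.56, -5.78 and -6.67 in the mutants, which was 382-fold, 860-fold and 1791-fold lower. Uty was not well above background on the control arrays and was at least 132-fold, 45.7-fold and 73.5-fold higher in the mutants. Eif2s3y was at least 42.9-fold, 44.7-fold and 79.5-fold higher, and Kdm5d at least 38.1-fold, 21.1-fold and 31.8-fold higher. Ddx3y was 27.8-fold, 10.1-fold and 13.6-fold higher, and the list median was 5.25, 4.40 and 4.99. The sex of the embryos is not given in the labels.

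**Figure D3:**
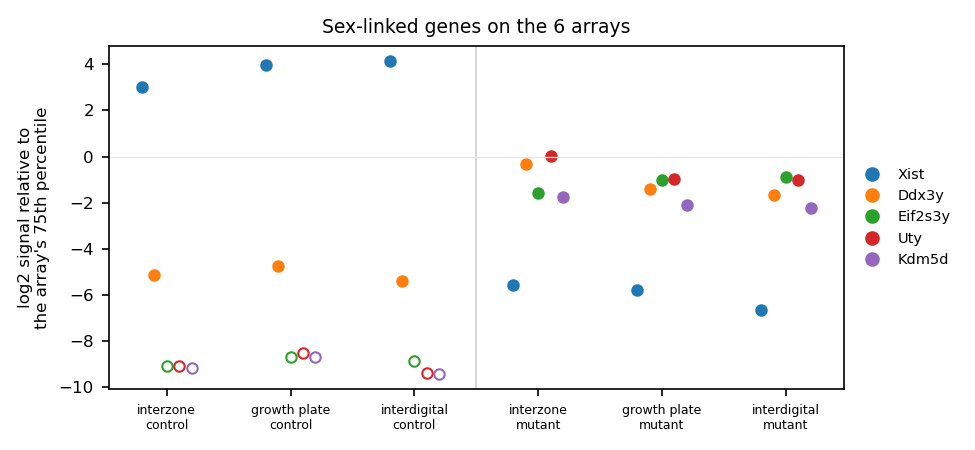
Log2 signal relative to the array's 75th percentile (vertical axis) of Xist and 4 Y-linked genes on the 6 arrays (horizontal axis), 1 point per gene and array, with open points for genes not well above background. Xist lay between 3.02 and 4.14 on the control arrays and between -6.67 and -5.56 on the mutant arrays.

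Among control tissues, the growth plate array had the highest cartilage levels and the interzone array the highest Gdf5. In control interzone against growth plate, 11 of 24 joint genes were higher and 3 lower (median 0.88), with Gdf5 4.46-fold and Htra1 42.5-fold higher. Cartilage (18 of 26 lower, median -1.81) and hypertrophic genes (8 of 13 lower, median -2.40) were lower, with Acan 5.94-fold, Matn3 19.7-fold and Ihh 15.9-fold lower in the interzone and Panx3 at least 3045-fold lower. Chemokine and receptor (median -0.61), muscle (-0.96) and epidermis lists (-1.16) were called lower in the interzone, and endothelium (1.73) and matrix proteases (0.83) higher. None of the 3 higher calls, joint genes included, held with the mean over a gene's probes, the epidermis call was lost there too and the chemokine call with normexp, and with the deposited ratio table the joint and matrix protease medians turned to -0.34 and -0.39.

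In control interzone against interdigital tissue, 13 of 24 joint genes were higher and 0 lower (median 1.39), with Gdf5 8.76-fold, Trps1 7.13-fold and Osr2 5.57-fold higher. Cartilage genes were higher (median 0.87), as were erythroid (1.29), epidermis (1.19) and hypoxia and glycolysis genes (0.81). Endothelium (11 of 15 lower, median -2.76) and macrophage genes (13 of 17 lower, median -2.27) were lower, as were osteoblast (-0.65), muscle (-0.54), matrix protease (-0.73), chemokine (-0.50) and TGF-beta target genes (-0.21). In control growth plate against interdigital tissue, 23 of 26 cartilage genes were higher (median 2.98), with Col2a1 4.45-fold and Matn1 32.3-fold higher. Epidermis genes were also higher there (median 2.76), with Dsp 317-fold higher, as were hypoxia and glycolysis genes (1.38). Interdigital mesenchyme (-1.27), endothelium (-4.46), Notch (-1.64) and matrix protease genes (-1.75) were lower. With the deposited ratio table the interdigital mesenchyme median turned to 0.19, and that of TGF-beta targets in interzone against interdigital tissue to 0.0313, while the epidermis, muscle and chemokine calls between those tissues and the Notch call were lost under other alternatives.

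Among mutant tissues the cartilage list no longer stood apart. Its median was 0.09 in interzone against growth plate, 0.22 in interzone against interdigital tissue and -0.23 in growth plate against interdigital tissue, each within the random lists. Joint genes were higher in mutant interzone than in mutant growth plate (median 0.63) and lower in growth plate than in interdigital tissue (-0.75), the first of these calls being lost with normexp. Mutant interzone had higher muscle genes than growth plate (1.98) and interdigital tissue (1.94), and lower cell cycle genes (-1.21 and -0.85). Whether a tissue difference differed between genotypes was not tested, since each genotype had 1 array per tissue.

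Tissue differences were little alike in the 2 genotypes. Pearson's r across 15589 genes was -0.03 for interzone against growth plate, 0.04 for interzone against interdigital tissue and 0.10 for growth plate against interdigital tissue. In the limma tissue fits, 0 genes passed for interzone against growth plate (1176 at an unadjusted p under 0.05), 0 for interzone against interdigital tissue (605) and 0 for growth plate against interdigital tissue (1050). The limma fits without 1 array also called 0 genes, while these unadjusted counts moved by over 1.5 times for some arrays. For interzone against growth plate the count was 3160 without the growth plate mutant array and 732 without either interdigital array. For interzone against interdigital tissue it was 1021 without the interzone control, 993 without either growth plate array and 397 without the interdigital mutant. For growth plate against interdigital tissue it was 3378 without the growth plate mutant and 492 without the interdigital control. Adjusted over the list alone, 6, 3 and 4 list entries passed. The alkaline phosphatase gene Alpl stands in both the hypertrophic and the osteoblast list and was counted in each. For interzone against growth plate the entries were Alpl, the ligand gene Fgf9, the platelet chemokine gene Pf4 and the interferon genes Irf9 and Rsad2. Alpl and Pf4 also passed for interzone against interdigital tissue, and Fgf9 and the interferon genes Ifit3, Irf9 and Rsad2 for growth plate against interdigital tissue.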

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

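The tests in this part were chosen only after the results were seen. Listed first are gene lists that went in opposite directions in mutant and control pairs of different tissues. Whether the tissues differed in these values was not tested, since each value compares 1 array with 1 array. The interzone and joint list had a median log2 difference of -1.08 in interzone and 0.43 in interdigital tissue. The muscle list was at 1.66 in interzone, -1.42 in growth plate and -0.75 in interdigital tissue. The endothelium list was at 1.07, 2.87 and -0.63 in the same order. The macrophage list was at 2.42 in interzone and -0.82 in interdigital tissue, and the cell cycle list at -1.02 in interzone and 0.50 in growth plate. With the deposited ratio table the growth plate value of cell cycle turned to -0.63, and the interdigital calls of the joint and endothelium lists did not hold under every alternative.

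Genes named here that differed at least 2-fold in opposite directions are given with their log2 differences, some of them bounds. The order is that of the tissues in each sentence, and the differences between tissues were not tested. Among 15589 genes detected on all 6 arrays, such genes numbered 1609 for interzone and growth plate, where independent tissues would give 1605. The counts were 699 against 684 for interzone and interdigital tissue, and 787 against 933 for growth plate and interdigital tissue. Opposite differences thus numbered close to or below what independent tissues would give, and the genes below mark no excess of them. Lower in interzone and higher in growth plate were Bub1b (-3.28 and 1.96), Cdc20 (-2.18 and 1.89), Coa4 (-6.85 and 3.11), Hes1 (-2.10 and 7.23), Jun (-1.78 and 3.95), Lypla1 (-6.93 and 3.47), Myo1c (-8.10 and 6.57), Sfrp1 (-7.93 and 3.66), Smim3 (-6.75 and 6.15) and Wif1 (-4.97 and 1.65). Higher in interzone and lower in growth plate were Actc1 (4.27 and -2.36), Bnipl (8.93 and -1.95), Laptm5 (3.28 and -8.39), Mttp (4.22 and -10.19), Myl1 (3.16 and -3.76), Mylpf (3.86 and -3.43), Myog (5.00 and -4.82) and Septin4 (8.07 and -2.93). Higher in growth plate and lower in interdigital tissue were Ccl11 (3.996 and -6.85), Dlx5 (1.52 and -1.77), Kdr (5.01 and -2.18), Klf1 (2.13 and -4.94) and Timp3 (5.00 and -1.31). Higher in interzone, higher in growth plate and lower in interdigital tissue were Acvrl1 (7.35, 6.29 and -2.10), C1qtnf9 (1.004, 5.55 and -6.70) and Tek (3.13, 6.44 and -1.22). Higher in interzone and lower in interdigital tissue were Atoh7 (3.09 and -5.12), Ccl12 (5.24 and -2.97) and Flt1 (3.87 and -1.31). Lower in interzone, higher in growth plate and higher in interdigital tissue were Chst5 (-6.76, 5.20 and 3.29), Has2 (-2.48, 1.41 and 1.87) and Tpbg (-1.83, 8.57 and 1.37). Higher in interzone, lower in growth plate and lower in interdigital tissue were Ostn (3.21, -6.06 and -7.29), Panx3 (5.72, -4.67 and -2.10) and Romo1 (1.45, -3.94 and -5.24). Lower in interzone, lower in growth plate and higher in interdigital tissue were Gdf5 (-2.25, -1.96 and 1.17) and Lmx1b (-3.21, -1.44 and 2.33). Lower in interzone and higher in interdigital tissue were Gdf6 (-4.77 and 2.03) and Osr2 (-1.72 and 1.58). Lower in interzone, higher in growth plate and lower in interdigital tissue were Ifi205 (-1.74, 3.27 and -4.85) and Rftn1 (-1.36, 3.16 and -6.61). Lower in growth plate and higher in interdigital tissue were Slc2a1 (-1.04 and 1.78) and Vdr (-10.66 and 1.12). Higher in interzone, lower in growth plate and higher in interdigital tissue was Ppp1r36 (5.06, -9.69 and 2.65). Some of these signs turned with the processing. Normexp gave 1.25 for Ifi205 and 1.57 for Rftn1 in interzone, and the mean over probes gave -0.0864 for Ifi205 and 1.29 for Bnipl in growth plate and -2.51 for Tpbg in interdigital tissue.

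Joint and cartilage genes were lower in the mutant interzone array and cartilage genes in the mutant growth plate array, and fewer cells of the main type in the capture is a candidate explanation. A loss that raised other cell types alike was weighed with 95% bootstrap intervals, made by resampling the genes of a list. These lay apart for 4 of 15 pairs of other-cell lists in interzone and for 3 of 15 in growth plate. This argues against it for these arrays only, since the intervals hold no variation between captures or embryos. In growth plate the 3 pairs set muscle or erythroid genes against endothelial or epidermal ones. Fewer chondrocytes beside unequal changes in other cell types stays open there. In interzone all 4 involved the erythroid list (median -0.84, within the random lists), while the other 5 lists had medians of 1.02 to 2.43 with intervals that overlapped, so fewer interzone cells beside more cells of those types stays open. Low detection on the control growth plate array stays open. The cartilage median for mutant growth plate minus interdigital was -0.23, with an interval of -0.56 to 0.38. This value does not use that control array, and it showed no cartilage excess in the mutant growth plate array. How large the excess is in control tissue is known only from the array in doubt, at 2.98, so the size of the loss could not be judged. For a difference between slides as the whole cause, the interdigital pair was split over the same slides. Its median was -0.55, with an interval of -0.97 to -0.09, against -3.55 and an interval of -3.91 to -3.09 in growth plate. This argues against a slide effect of like size in both pairs. A slide effect that differed between captures, or joined the low detection on that control array, cannot be told apart with 1 array per group. Genotype stays open and untested, as do sex, embryo and the position of the captured cells, since each group had 1 array.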

How the results depend on the processing

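The alternatives were planned beforehand, except fits over all gene names and pair counts over genes detected on all 6 arrays, which were chosen only after results were seen. Every alternative was run, and the cause of the shifts below was not tested unless stated. By embryo, no paired analysis was possible because the labels do not say which embryo stood behind each array; the genotype fit pairs arrays by tissue. Signal over background limits dim genes, which have only bounds, most of all on the growth plate control array with 72.3% of spots detected. Of counts of genes, 158 values stayed within 1.5 times the main count and 12 moved. Most of the 158 were limma counts of 0 against a main count of 0, which say little about stability. Of correlations 31 stayed and 11 moved, of numbers of lists called 115 stayed and 11 moved, and of values of single lists 517 kept the call, 64 lost it, 14 reversed and 51 came from lists called only under an alternative. For named genes other than Tgfbr2, 834 values stayed within the spread of replicate spots, 1421 moved and 15 reversed.

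With normexp correction, the interzone pair had 5340 genes higher and 2129 lower. With the deposited ratio table, the growth plate pair had 2110 higher and 10446 lower, and the genotype fit called 12 higher and 1 lower. At 4-fold, which by construction passes fewer genes, the counts were 1309 and 1729 in interzone, 2232 and 1981 in growth plate, and 599 and 685 in interdigital tissue. Over genes detected on all 6 arrays, the 2-fold counts were 2597 and 3528, 3479 and 4907, and 1377 and 2238.

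The correlation across genes of mutant differences was 0.0230 between interzone and growth plate with normexp and 0.0522 with quantile normalization. Between interzone and interdigital tissue it was 0.0706 with normexp and 0.122 as a rank correlation. For tissue differences across genotypes, quantile normalization gave -0.0813 for interzone against growth plate, 0.112 for interzone against interdigital tissue and 0.179 for growth plate against interdigital tissue. The mean over probes gave -0.0532 and 0.0865 for the first pair of these, detection on at least 1 array 0.0710 for interzone against interdigital tissue, and rank correlation -0.0060 for interzone against growth plate.

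In the growth plate pair, 3 lists were lower with quantile normalization, 8 higher with the mean over probes and 3 higher with only members detected on both arrays. Lists higher in control interzone against growth plate numbered 0 with the mean over probes and 1 with unmatched random lists, and 2 in the mutants with unmatched random lists. Lists lower in mutant interzone against interdigital tissue numbered 3 with quantile normalization, 1 with the mean over probes and 3 with unmatched random lists. Lists higher in mutant growth plate against interdigital tissue numbered 2 with normexp and 2 with the mean over probes.

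Of 12, 10 and 12 lists called in the interzone, growth plate and interdigital pairs, 7, 5 and 7 kept the call under every alternative run. In interzone these were joint, cartilage, muscle, endothelium, macrophage, epidermis and cell cycle, and those that did not hold were tendon and ligament, nerve and Schwann cell, hedgehog, Wnt and sex-linked. In growth plate cartilage, hypertrophic cartilage, muscle, endothelium and epidermis held, and erythroid, TGF-beta pathway components, cell cycle, immediate early and stress, and sex-linked did not. In interdigital tissue hypertrophic cartilage, osteoblast, muscle, macrophage, epidermis, FGF and hypoxia held, and joint, cartilage, endothelium, nerve and Schwann cell, and sex-linked did not. Among control tissues, 3 of 8 calls held for interzone against growth plate, 8 of 12 for interzone against interdigital tissue and 6 of 11 for growth plate against interdigital tissue, and among mutant tissues 4 of 6, 2 of 6 and 3 of 8.

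Reversed list medians were 0.18 for Wnt signalling in interzone with normexp, -0.0791 for TGF-beta pathway components and -0.63 for cell cycle in growth plate with the ratio table, and -0.0535 for nerve and Schwann cell in interdigital tissue with the mean over probes. With only members detected on both arrays, sex-linked genes had -1.89, -3.20 and -3.52 in interzone, growth plate and interdigital tissue, because only Xist and Ddx3y remained. Among control tissues the ratio table reversed joint (-0.34) and matrix protease genes (-0.39) in interzone against growth plate, TGF-beta targets (0.0313) in interzone against interdigital tissue, and interdigital mesenchyme (0.19), TGF-beta pathway components (0.41) and hedgehog (0.63) in growth plate against interdigital tissue, and normexp reversed Notch (0.44) in mutant interzone against interdigital tissue. The Tgfbr2 difference with the ratio table was 0.0514, 2.49 and -0.41 in the same order. In growth plate it was also 3.27 with normexp, 2.94 with quantile normalization, 3.98 with the percentile over detected probes and 2.46 with the mean over probes, and in interdigital tissue -1.37 with the mean over probes.

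Among named genes with a difference of at least 2-fold, the mean over probes turned growth plate values to 0.19 for Bmp5, 1.29 for Bnipl, 2.21 for Hhip, -0.0864 for Ifi205 and -0.0824 for Tprg, interdigital values to -0.16 for Ifit3 and -2.51 for Tpbg, and the interzone value of Frem2 to -0.81. Normexp turned interzone values to 0.25 for Dnajc22, 1.25 for Ifi205, 1.34 for Mcoln2, 2.25 for Pf4, 1.57 for Rftn1 and 1.94 for Tnfsf11. The ratio table turned Tprg in growth plate to -0.11.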

Other observations

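The test of sex-chromosome genes and the second epidermal list below were set down before their results were seen, and the other tests were chosen only after the result was seen. BMP and GDF medians were -0.27, -0.01 and 0.05 in interzone, growth plate and interdigital tissue, within the random lists, while the ligand gene Bmp5 was 8.36-fold, 26.4-fold and 3.37-fold lower in the 3 mutant arrays, the growth plate value turning to 0.19 with the mean over its probes. Notch medians were -0.66, 1.30 and -0.03, and the effector gene Hes1 was 4.28-fold lower in interzone and 150-fold higher in growth plate. Chemokine and receptor medians were 0.02, -0.48 and -0.59, with the platelet chemokine gene Pf4 18.8-fold and 5.23-fold lower in growth plate and interdigital tissue. Matrix protease medians were -0.10, -0.05 and -0.40, with the cathepsin gene Ctsk 19.5-fold, 29.6-fold and 2.09-fold lower and Adamts9 79.0-fold, 6.33-fold and 3.88-fold lower.

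The apoptosis, interferon response, posterior Hox, housekeeping and interdigital mesenchyme lists stayed within the random lists in all 3 pairs. For growth plate this says little, since simulated lists shifted by 1 on the log2 scale were called there in 27.5% of cases. The same limit holds for the growth plate medians of TGF-beta target, BMP and GDF, Notch, chemokine and matrix protease genes. Apoptosis medians were 0.44, -0.62 and -0.04, with the p53 target Pmaip1 74.0-fold, 46.7-fold and 1.36-fold higher. Interferon response medians were -0.14, -0.90 and -0.40, posterior Hox medians -0.72, -0.54 and -0.41, and housekeeping medians 0.17, -0.30 and 0.21. Interdigital mesenchyme medians were 0.05, -0.55 and -0.02, with Bmp7 3.17-fold higher and Adamts9 3.88-fold lower in interdigital tissue itself.

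Other splits of the 6 arrays into 3 and 3 were fitted for the genotype result with limma. The real split called 0 genes and the highest of the others 0. Since limma recovered 0% of simulated changes at this noise, this count says little. At an unadjusted limma p under 0.05 there were 1191 genes in the real split and at most 3376 in another, where only the growth plate pair was divided. Splits that divide a single tissue pair repeat each other, with counts of 3376, 1107 and 150. They are unlike the real split, which divides all pairs. The other splits that divide all pairs had 450, 555 and 593 genes at an unadjusted limma p under 0.05, fewer than the real split. The 10 splits are too few for a share under 0.05.

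Xist was lower and Y-linked genes were higher in each mutant array, and embryos of different sex in the 2 genotypes are a candidate explanation. All 18 values of Eif2s3y, Uty and Kdm5d lay on the side this needs, but they are part of the pattern itself and so test nothing further. These genes were not well above background on any control array and were on every mutant array, while Xist was high on the control arrays only. For these 6 arrays this argues against material of the same sex in both genotypes, and it is the pattern of female control and male mutant material. An exchange of an array between genotypes would leave arrays unlike the others of their genotype, and 0 were. This too is part of the pattern itself, and an exchange of all arrays would look the same. Sex-chromosome genes as the whole cause of the shared differences are argued against. Of the 547 genes that differed the same way in all 3 pairs, 5.85% lie on X or Y. That share was 3.25% among the 15589 genes detected on all 6 arrays, from which the 547 came. Eif2s3y, Uty and Kdm5d are not among them, being not well above background on the control arrays. The share does not bear on effects of sex on genes of other chromosomes. Sex, genotype and embryo remain open as sources of any shared difference, because they run together in this design.

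Epidermal genes were higher in the mutant arrays, and epidermal cells in the captured material are a candidate source, since skin lies close to these tissues. A second list of 20 epidermal genes, from which 6 genes already seen in the results had been removed, was above the random lists in 2 of 3 pairs, with medians of 1.62 in interzone, 0.49 in growth plate and 1.42 in interdigital tissue. The growth plate median was at percentile 97.2, narrowly inside the random lists, and its bootstrap interval of -0.60 to 1.71 reached beyond them, so the bound set beforehand was met there by less than its spread and, as settled after the value was seen, decides nothing. Genotype as the whole cause was set against the control arrays, where growth plate exceeded interdigital tissue in epidermis genes by a median of 2.76, with an interval of 0.77 to 5.45 that reaches below the bound of 1. Neither explanation was excluded, Krt14 and Krt10 reached levels of 4.83 and 5.47 in mutant growth plate, and how far embryonic mesenchyme itself expresses these genes was not tested.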
